A study of Mus musculus with 5 samples.

How the data were processed

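Liver RNA was measured on 5 Affymetrix Mouse430_2 arrays, 1 for each of the inbred mouse strains C57BL/6J, BALB/CByJ, FVB/NJ, NZW/LacJ and RIIIS/J. Per the labels, each array was hybridised with RNA pooled from 3 untreated males of 10 weeks. RNA was extracted with Trizol and RNeasy and labelled with the manufacturer's kits. The deposited values are given in the unit intensity, on a linear scale, and were made by the authors with GCOS and GCRMA per the submitters' processing notes. Versions and settings of those programs, the time of day of collection and the array batches were not given in the sources used here. The genotyping data that the design text mentions were not used here.

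The table held 45101 probe sets, of which 64 were manufacturer controls. By the annotation of the platform 34970 probe sets had 1 gene, 920 had several and 9211 had none, and those with several or none were left out of the gene values. Of the probe sets with 1 gene, 34754 matched the mouse reference gene table, which served only for names and for the order of genes along the chromosomes. The array table names no genome build, so no coordinates are given. Among all probe sets, 29.1% had exactly equal values on at least 2 arrays, and this share was 36.4% among those above the floor on all arrays.

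Intensities were converted to log2. Each of 18205 genes took the value of its probe set with the highest mean over the 5 arrays. A floor for detection was set at the 95th percentile of 83 probe sets for olfactory, vomeronasal and taste receptors, at an intensity of 8.49 or 3.09 on the log2 scale. By this floor 11862 genes were detected on at least 1 array and 10342 on all 5. The number detected per array was 11105 for C57BL/6J, 10772 for BALB/CByJ, 10992 for FVB/NJ, 11068 for NZW/LacJ and 11021 for RIIIS/J. Values under the floor were raised to it before differences were taken, so a fold against such a value is a lower bound and is written as "at least". List medians were taken with these raised values too, and a median that rests on them is a bound.

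With 1 array per strain there was no replicate check, no test was run and no p-value is given, and the number of arrays limits the precision of every comparison. A gene was called apart in a strain when it was at least 2-fold above, or at least 2-fold below, the nearest of the other 4 strains. Pairs of strains were compared by counting the genes at least 2-fold apart between them. For 41 gene lists, the log2 value of a strain minus the mean of the other 4 was taken for each detected member, and the median was placed among 10000 random lists matched over 20 bins of expression. Lists with at least 5 detected members were called apart under the 2.5th or above the 97.5th percentile, which describes these arrays and carries no error between animals. Where a called gene had a further detected probe set, the direction of that probe set was checked. Adjacent genes called apart the same way in the same strain were counted and compared with 10000 shuffles of gene order. Signals of the poly-A and hybridisation controls, and the ratio of 3' to 5' probe sets of actin and Gapdh, were read alongside.

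The main settings, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule named, per strain and direction, the 8 genes with the largest measured gap and the 4 with the largest lower bound, and members of the gene lists. Genes named to show a split of the strains into 2 and 3, and the named pairs of neighbours, were chosen after their values were seen. A further 10 lists and the settings that leave out arrays were also chosen after seeing the data. The alternatives were a floor at the 99th percentile of the receptor probe sets (intensity 28.2), no floor, the mean of a gene's probe sets, removal of probe sets whose names end in _s_at, _x_at or _a_at, quantile normalisation, a loess correction with span 0.3, a 4-fold threshold, comparison with the median of the other strains or with C57BL/6J alone, and single probe sets of the named genes. No paired analysis was possible because each strain had 1 array.

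The procedure was tested on simulated data built on the FVB/NJ array. Genes raised by 0.5 on the log2 scale were called in 0 of 66 cases, those raised by 1.5 in 66 of 67 and those raised by 2.5 in 67 of 67. Among genes left as they were, 0 of 18005 were called, and 30 of 30 planted pairs of neighbours were found. The pairs were planted directly as gaps, with all other gaps at 0, so finding them checks only the counting. The noise was small and set by hand, and the raised genes were drawn from those well above the floor. On the real arrays the deviations of 2 probe sets of a gene differed by a median of 0.21 log2, with a 95th percentile of 0.999. The simulated counts therefore check the steps and give no error rate for these arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used, with the random seed 1.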

Results

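The series asked how hepatic expression differs among inbred strains, as a follow-up of expression loci found elsewhere. Hepatocyte genes were close across the 5 arrays. Alb, the serum albumin gene, read 63745 to 74714, Ttr read 59490.1 to 67939 and Hnf4a, a hepatocyte transcription factor gene, read 3203 to 3591. The Y-linked genes Kdm5d (118 to 164), Eif2s3y (738 to 1202) and Uty (61.7 to 150) were detected on every array, and the X-inactivation transcript Xist (6.04 to 7.04) was under the floor on every array. Genes apart from each other strain numbered 58 higher and 50 lower in C57BL/6J, 95 and 52 in BALB/CByJ, 690 and 64 in FVB/NJ, 90 and 86 in NZW/LacJ, and 115 and 205 in RIIIS/J. Without the RIIIS/J array NZW/LacJ had 158 higher and 189 lower genes. Oxidative phosphorylation, apolipoprotein, hepatocyte, cholangiocyte, iron handling, serpin and xenobiotic cytochrome P450 lists were apart in none of the 5 strains. Some lay close to the limits. Oxidative phosphorylation in FVB/NJ stood at -0.22 (percentile 2.59), with 0 of 29 members above the mean of the others. The xenobiotic list in RIIIS/J was at percentile 97.465. Hepatocyte markers had 1 of 12 members above the mean of the others in FVB/NJ, and likewise 1 of 12 in BALB/CByJ.

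**Figure D1:**
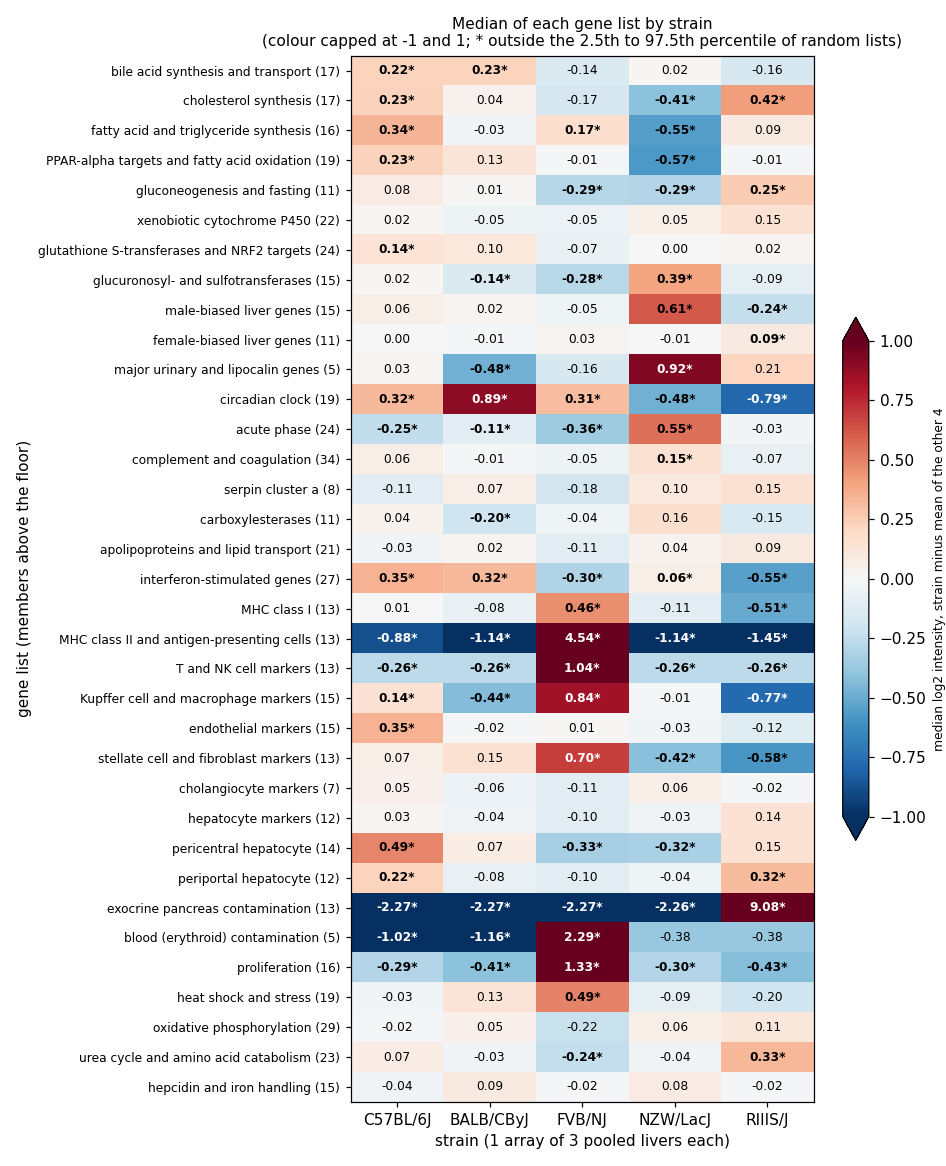
Median log2 intensity of each gene list in each strain (columns, 1 array each) minus the mean of the other 4 strains, with the number of detected members in brackets and stars for medians outside the middle 95% of random lists. The exocrine pancreas list has a median of at least 9.08 in RIIIS/J and the antigen-presenting list one of at least 4.54 in FVB/NJ, while the circadian list runs from 0.89 in BALB/CByJ to -0.79 in RIIIS/J.

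A list of 22 genes with strain differences known from elsewhere, 16 of them detected, was apart in none of the 5 strains as a whole, with medians from -0.06 in RIIIS/J to 0.16 in BALB/CByJ. Nnt, the mitochondrial transhydrogenase gene, read 708 in C57BL/6J against 1616 to 2475 in the other strains. Alad and Hdhd3, which lie together in a segment that varies in copy number among strains, were lowest in C57BL/6J, at 4257 against 8396 to 12311 and at 105 against 194 to 806. Hc, the complement C5 gene, was lowest in FVB/NJ at 3858 against 8899 to 18320. Wdfy1 was lowest in C57BL/6J (228 against 436 to 593). Pttg1, the securin gene, read 3948 in C57BL/6J against 166 to 552. Zhx2, a repressor of fetal liver genes, was under the floor in BALB/CByJ and read 36.9 to 77.7 elsewhere, at least 4.35-fold higher. Whether BALB/CByJ carries a variant of Zhx2 could not be read from the sources used here. Afp, the fetal alpha-fetoprotein gene, was highest in BALB/CByJ at 149 against 17.9 to 40.6. Acads, a short-chain acyl-CoA dehydrogenase gene with a known variant in BALB/CByJ, was not lower there, at 967 against 629 to 900.1. Other members were Glo1 (9083 to 17722), Ide (982 to 1729), Fcgr2b (535 to 886), Vwf (44.4 to 113) and Ifi202b (10.5 to 39.9). Klra8 (7.43 to 9.56) and Apobec3 (8.27 to 8.54) were near the floor.

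C57BL/6J was compared with the other strains first. Cyp4a14, a fatty acid hydroxylase gene induced through the nuclear receptor PPAR-alpha, read 3880 in C57BL/6J against 9.71 to 86.9 in the other 4 strains, 44.6-fold above the nearest. Vnn1, a pantetheinase gene, read 2557 against 33.0 to 45.5, and the adjacent Vnn3 read 1169 against 123 to 292. Cd36, a fatty acid transporter gene, read 1027 against 148 to 467. The list of PPAR-alpha targets and fatty acid oxidation had 19 detected members and a median of 0.23 (99.9th percentile). Fatty acid and triglyceride synthesis stood at 0.34, with 14 of 16 members above the mean of the other strains, among them Fasn (2725 against 829 to 2037) and Acacb (389 against 184 to 249). Cholesterol synthesis stood at 0.23, with Sc5d at 12212 against 5334 to 6909. Pericentral hepatocyte genes had a median of 0.49 and 12 of 14 members above the mean of the other strains, including Glul (9787 against 4947 to 7027), Slc1a2 (1071 against 166 to 473) and Lgr5 (56.1 against 24.8 to 30.2). Periportal hepatocyte genes were called higher too, at 0.22 with 9 of 12 members above the mean, a call kept in 6 of 10 other settings. Bile acid genes stood at 0.22 and endothelial markers at 0.35, with 13 of 15 endothelial members above the mean. Pltp, which encodes a phospholipid transfer protein, read 5238 against 802 to 1412. Igfbp1, an insulin-repressed gene, read 788 against 114 to 260, and Asns read 60.2, 3.84-fold above the nearest strain. The PPAR-alpha, fatty acid synthesis, cholesterol and pericentral lists were lower in NZW/LacJ (-0.57, -0.55, -0.41 and -0.32), and every setting kept that array. Part of their higher medians in C57BL/6J may mirror it, though each of these calls was kept in 10 of 10 other settings.

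The acute phase list was lower in C57BL/6J, at -0.25 over 24 members, a call kept in 10 of 10 other settings. It was also called lower in BALB/CByJ (-0.11) and FVB/NJ (-0.36), and higher in NZW/LacJ (0.55). The other strains set against C57BL/6J included NZW/LacJ in every setting, so part of the lower median may mirror that array. Among the members, the metallothionein genes Mt1 (1460 against 3372 to 7021) and Mt2 (228 against 855 to 2201) were adjacent and both apart. Lcn2 read 14.1 against 32.7 to 261. Hddc3 was 15.0-fold below the nearest strain, at 12.99 against 195 to 599, and Gpat3, a glycerol phosphate acyltransferase gene, was 8.05-fold below. Vcpkmt was 4.50-fold and Tmem87a 3.82-fold below. Pik3ap1 was 11.2-fold below on its most intense probe set, and another of its probe sets read 50.2 against 36.1 to 56.5. Cyp2c39 was at least 2.30-fold, Ttc28 at least 3.03-fold and Prelid2 at least 2.95-fold lower. Apoa4 was apart at 486 against 1379 to 1860, and Tfrc, the transferrin receptor gene, at 337 against 874 to 1432. Higher genes without a listed role included Zfp874a (at least 38.6-fold), Gm7969 (at least 30.1-fold) and Olig1 (at least 17.4-fold). Interferon-stimulated genes stood at 0.35 in C57BL/6J, and at 0.028 when FVB/NJ and RIIIS/J were left out.

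BALB/CByJ was apart in single genes of hormone, protease and pheromone carrier function. Dio1, which encodes the deiodinase that activates thyroid hormone, read 55.3 in BALB/CByJ against 2533 to 4960, 45.8-fold below the nearest strain. Mup10 and the adjacent Mup5, genes for major urinary proteins, were lower by at least 576-fold and by 7.92-fold, and Mup5 read 32.8 against 259 to 306. Capn3, a calpain protease gene, read 216 against 9.56 to 9.78. Sult1c2 read 365 against 48.8 to 69.4, whereas Sult5a1 was 7.61-fold below the nearest strain. Lpl, the lipoprotein lipase gene, read 3414 against 318 to 1590, 2.15-fold above the nearest. Apom, an apolipoprotein gene, read 4379 against 9145 to 15615. Further genes below the nearest strain were Plscr2 (11.9-fold), Camk1d (10.1-fold), Fitm1 (9.04-fold), Tmem51 (5.19-fold) and Tifa (5.02-fold). The inflammasome gene Nlrp12 was at least 18.2-fold and the chemokine gene Ccl27a at least 7.17-fold lower. Genes above the nearest strain included Nbdy (7.39-fold), Atp6v0e2 (6.59-fold), Spc25 (5.34-fold), Slc25a48 (4.69-fold), Cox6b2 (16.8-fold) and Iqca (at least 20.9-fold).

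The circadian clock list was higher in BALB/CByJ, with a median of 0.89 over 19 members at the 100th percentile. The list mixes genes of opposite phase. In BALB/CByJ those that peak near dusk had a median of 1.33 and those that peak near dawn one of -0.74, with the same signs in C57BL/6J and FVB/NJ. The same list was also called higher in C57BL/6J (0.32, percentile 99.98) and FVB/NJ (0.31, percentile 99.5), and the BALB/CByJ median was 0.24 against C57BL/6J alone, where the FVB/NJ median was 0.0079 and its call ended. Ciart, a clock repressor gene, read 212 against 16.3 to 75.6, and Noct, a rhythmic phosphatase gene, read 1077 against 24.5 to 479. Dbp read 8951 against 75.5 to 6439. Kupffer cell and macrophage markers were lower at -0.44, with Cd5l at 520 against 614 to 1678 and Adgre1 at 47.6 against 37.3 to 123. The major urinary and lipocalin list stood at -0.48 and glucuronosyl- and sulfotransferases at -0.14. Bile acid genes stood at 0.23, with Cyp7b1 at 29104 against 10929 to 25659 and Abcg8 at 994 against 177 to 575. Carboxylesterases stood at -0.20, a median set by Ces4a, which was under the floor in RIIIS/J and was raised to it. Of 11 other settings, 8 kept the call of the urinary and lipocalin list, 7 those of the transferases and of the bile acid genes, and 5 that of the carboxylesterases, whose median was 0.035 with the floor at the 99th percentile. The bile acid median was 0.057 (72.8th percentile) without the FVB/NJ array and 0.17 (96.5th percentile) without the RIIIS/J array.

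FVB/NJ was set apart by genes of lymphoid and blood cells. Ighm, the immunoglobulin mu heavy chain gene, read 11859 in FVB/NJ, 66.6-fold above the nearest strain, and the B cell receptor gene Cd79b read 3041, 112-fold above. Ms4a1, which encodes CD20, was 67.3-fold and Cd79a at least 106-fold higher. Slc4a1, the erythrocyte anion exchanger gene, read 1096, 82.3-fold above the nearest strain. Antigen-presenting genes had a median of at least 4.54, with 10 of 13 members apart, led by Cd74 (9250 against 93.7 to 651) and H2-Ab1 (4259 against 50.6 to 386). Members of that list that were not higher were H2-Eb1 (47.1 against 33.1 to 274) and H2-Ea (73.6 against 40.3 to 204). The T and NK cell list had a median of at least 1.04, with Cd3d at 165 and Ccl5 at 42.7, while Cd8a was level at 14.1 to 14.2 and Cd4 was near the floor at 8.21 to 9.74. Among 15 Kupffer cell and macrophage markers the median was 0.84, with Marco at least 20.2-fold higher, Timd4 at 56.5 against 8.61 to 10.8 and Lyz2 at 1749 against 460 to 747. Clec4f (600 against 537 to 1152) and Cd163 (118 against 95.9 to 282), also Kupffer cell genes, were not higher. Of 5 erythroid genes (median 2.29), Hbb-b2 read 1139 against 22.7 to 76.2 on its most intense probe set, with a further probe set deviating by -0.45 on the log2 scale, and Bpgm read 938 against 150 to 213. The neutrophil genes S100a8 (152 against 10.3 to 21.8) and S100a9 (422 against 9.45 to 35.9) were higher. Cell division genes had a median of at least 1.33 with 9 of 16 apart, including Mki67 (at least 24.3-fold) and Mcm5 (635 against 60.9 to 94.3). The stellate cell and fibroblast list stood at 0.70, with Acta2 at 823 against 58.1 to 77.9 and Vim at 1251 against 312 to 535. Immunoglobulin segments Ighv14-2 (158-fold), Igkv8-30 (72.5-fold) and Igkv9-120 (at least 115-fold), and the leukocyte genes Coro1a (87.5-fold), Cd24a (81.3-fold), Pou2af1 (at least 59.2-fold) and Lsp1 (at least 57.6-fold), were also among the named genes. The calls of the T and NK, erythroid and stellate cell lists were each kept in 8 of 9 other settings, and the other list calls of this paragraph in all 9.

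**Figure D2:**
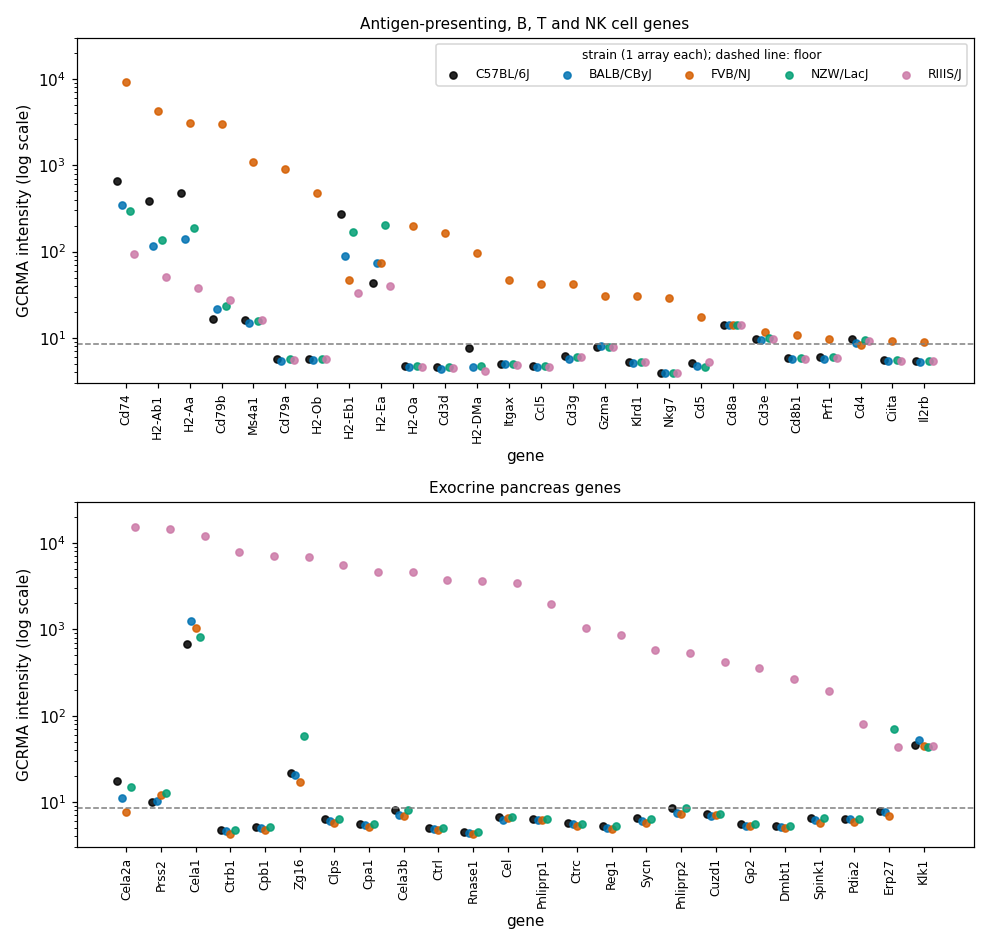
GCRMA intensity on a log scale for genes of antigen-presenting, B, T and NK cells (upper panel) and of the exocrine pancreas (lower panel), with 1 point per strain and a dashed line at the floor of 8.49. FVB/NJ reads 9250 for Cd74 in the upper panel and RIIIS/J reads 14380 for Prss2 in the lower panel, where the other strains read 10.1 to 12.8.

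Genes and lists other than the lymphoid and blood lists were also apart in FVB/NJ, though which cells gave their signal was not examined. List medians were not centred on 0 on this array, where hepatocyte markers at -0.10 lay at percentile 42.1. Cth, a gene of cysteine synthesis, read 2862 against 8986 to 13991, and the list of urea cycle and amino acid catabolism stood at -0.24 over 23 members. Gluconeogenesis genes stood at -0.29 and pericentral genes at -0.33, with Got1 at 1485 against 3010 to 7056. Yae1d1 was 9.66-fold, Ctsf 4.87-fold, A2ml1 4.43-fold, Slc13a2 4.35-fold and As3mt, an arsenic methyltransferase gene, 3.49-fold below the nearest strain. Hsd17b13, a lipid droplet protein gene, read 195 against 8338 to 10015 on its most intense probe set, while another of its probe sets was higher in FVB/NJ by at least 5.36 on the log2 scale, being under the floor in the other strains. The acute phase list was lower at -0.36, a call kept in 8 of 9 other settings and ended at -0.11 against C57BL/6J alone, and interferon-stimulated genes stood at -0.30. Within the interferon list Ifih1 was apart on the low side (278 against 562 to 642), while Rsad2 (1358 against 115 to 218), Gbp2 (104 against 9.89 to 33.3) and Trim30a (193 against 16.8 to 51.1) were apart on the high side. Heat shock genes stood at 0.49 with 15 of 19 members above the mean of the others. Hmox1, the heme oxygenase gene, read 373 against 22.2 to 134, and Cyp2b10, a xenobiotic hydroxylase gene, read 925 against 62.2 to 392. Of 9 other settings, 3 kept the call of the gluconeogenesis list (medians -0.30 to -0.085), 4 that of the urea cycle list and 5 that of the pericentral list (-0.87 to -0.13). Without the RIIIS/J array these 3 medians were -0.21, -0.19 and -0.13, and all 3 calls ended.

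NZW/LacJ was apart in secreted inflammatory proteins and in lipid metabolism. Saa1 and the adjacent Saa2, serum amyloid A genes, read 18765 against 449 to 1310 and 5624 against 80.1 to 225, 14.3-fold and 24.95-fold above the nearest strain. Lcn2, a siderophore-binding protein gene, read 261 against 14.1 to 37.1. The adjacent Orm3 (45.1 against 8.95 to 13.9) and Orm2 (776 against 94.7 to 350) were apart as well. The acute phase list stood at 0.55 with 22 of 24 members above the mean of the others, including Apcs at 21309 against 2782 to 12028. Complement and coagulation genes stood at 0.15, with C8b at 11740.4 against 4974 to 8722. Defb1, a defensin gene, was 29.3-fold, Pilra 13.9-fold, Ptgds 9.29-fold, Chic1 7.63-fold and Bace2 7.09-fold above the nearest strain. Mgst2, a microsomal glutathione transferase gene, read 1978 and was at least 233-fold higher, Myom2 was at least 174-fold, Cxcl14 at least 31.5-fold and Akr1c18 at least 26.8-fold higher.

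Lists of lipid synthesis and oxidation were lower in NZW/LacJ, while apolipoproteins and lipid transport (0.036) and bile acid genes (0.022) were not apart. Fatty acid and triglyceride synthesis stood at -0.55, with Elovl6 at 299 against 874 to 1525 and Fads2 at 1307 against 2931 to 5207. Cholesterol synthesis stood at -0.41 with 0 of 17 members above the mean of the others, and Hsd17b7 read 433 against 916 to 1336. PPAR-alpha targets stood at -0.57, with Cyp4a14 at 9.71, Cpt1a at 1141 against 1908 to 3218 and Acadm at 4861 against 6928 to 7811. Male-biased liver genes were higher at 0.61, with 14 of 15 above the mean, among them Susd4 at 1659 against 41.3 to 435, Ugt2b38 at 3468 against 185 to 1056 and Sult5a1 at 894 against 45.0 to 398. The major urinary and lipocalin list stood at 0.92 over 5 members, with Obp2a at 811 against 6.38 to 159. Serpina12, which encodes the adipokine vaspin, read 11999 against 490 to 3525. Stellate cell markers stood at -0.42 and pericentral genes at -0.32. Genes below the nearest strain were Gm4951 (48.8-fold), Cbr1, a carbonyl reductase gene (14.3-fold), Akr1c12 (13.1-fold), Noct (10.4-fold), Dcakd (8.17-fold), Gda (7.14-fold) and Gbp7 (6.58-fold). Reep3 was 23.98-fold lower on its most intense probe set, and a second probe set read 21.4 against 893 to 1449, while the gaps on its other 4 detected probe sets were -0.23 to -0.54 on the log2 scale. Of 11 other settings, 8 kept the calls of the complement, the urinary and lipocalin, and the stellate cell lists, the last of which stood at -0.15 without the FVB/NJ array, and the complement list stood at 0.095 without the RIIIS/J array. The pericentral call was kept in 10 of 11. Genes lower by a bound were 1700001C19Rik (at least 16.2-fold), Gm2788 (at least 11.6-fold), Cyp2g1 (at least 2.73-fold) and Bcl2l11 (at least 2.67-fold).

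RIIIS/J was set apart by genes of the exocrine pancreas. Prss2, a trypsinogen gene, read 14380 in RIIIS/J against 10.1 to 12.8 in the other strains, 1120-fold above the nearest. Cela1, an elastase gene detected on every array, read 12031 against 667 to 1256, and Cela2a was 883-fold higher. Ctrb1 was at least 921-fold and Cpb1 at least 832-fold higher, and Zg16, a zymogen granule gene, read 6974, 119-fold above the nearest strain. All 13 detected members of the pancreatic list were apart, and their median was at least 9.08. The trypsinogen gene 2210010C04Rik was 1922-fold and Pla2g1b, a pancreatic phospholipase gene, 5.44-fold higher. Outside this group Cyp2c38, a cytochrome P450 gene, read 7063 against 118 to 376, G6pc, the glucose-6-phosphatase gene, read 5504 against 1243 to 2036, and Pdk4 read 277 against 50.8 to 80.0. Ndrg1 was 6.10-fold, Appbp2os 5.77-fold and Mpst 5.70-fold above the nearest strain, and a further probe set of Appbp2os deviated by 0.0034 on the log2 scale. Urea cycle and amino acid catabolism genes stood at 0.33 with 19 of 23 above the mean of the others, including Aass (10449.5 against 5176 to 6908). Cholesterol synthesis stood at 0.42 with 13 of 17 above, including Pmvk (1280 against 561 to 748), and periportal genes at 0.32. The call of the cholesterol list was kept in 8 of 9 other settings and the periportal call in 5 of 9, with medians from 0.053 to 0.38, and its median was 0.11 (percentile 84.1) without the FVB/NJ array.

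Genes lower in RIIIS/J were more numerous than in any other strain. Pm20d1, which encodes an enzyme forming N-acyl amino acids, read 21.8 against 3301 to 6300, 151-fold below the nearest strain. Erdr1 read 19.01 against 1383 to 1651, Hnmt, a histamine methyltransferase gene, read 20.6 against 482 to 820, and Hao1, the glycolate oxidase gene, read 418 against 4897 to 8168. Egr1, an immediate early gene, read 20.4 against 267 to 791. Interferon-stimulated genes stood at -0.55 over 27 members, with Bst2 at 491 against 1319 to 2807, Ifit3 at 14.2 against 49.0 to 204 and Gbp3 at 29.1 against 60.7 to 125, while Oasl1 (103 against 7.64 to 60.2) was highest here. Ifi27l2a was at least 13.4-fold lower. MHC class I genes stood at -0.51, with H2-K1 at 2602 against 6160 to 11912 and H2-D1 at 3395 against 6789 to 15684. The MHC class II genes H2-Aa (37.7 against 141 to 3105) and H2-Ab1 (50.6 against 116 to 4259) were adjacent and both apart. Kupffer cell and macrophage markers stood at -0.77, with Ctss at 547 against 892 to 3719, and stellate cell markers at -0.58, a call kept in 8 of 9 other settings and ended at -0.27 with the mean of all probe sets, with Col3a1 at 304 against 495 to 1191. Male-biased genes stood at -0.24, a call kept in 7 of 9 other settings, and C9 read 7937 against 19139 to 28298. Rarres1 was at least 110-fold, Ttll1 at least 13.4-fold and Ctla2b at least 5.71-fold lower, and Lrit1 was 13.3-fold lower. A further probe set of Ttll1 deviated by -0.022 on the log2 scale. Gsn, the gelsolin gene, was 23.6-fold lower on its most intense probe set. Other Gsn probe sets read 29.7 against 104 to 896 and 51.1 against 128 to 981, and 1 had a gap of -0.19 on the log2 scale.

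Clock genes divided the 5 arrays into the same groups in both directions. Dbp, a clock output gene, read 1023 in NZW/LacJ and 75.5 in RIIIS/J against 4940 to 8951 in the other 3 strains. Usp2 read 55.3 and 23.4 against 718 to 930, and Per2 read 29.0 and 22.7 against 87.7 to 188. Arntl, which encodes BMAL1, went the other way, at 68.1 and 156 against 13.7 to 14.1, as did Clock (723 and 756 against 214 to 286) and Nfil3 (644 and 840 against 222 to 274). The whole circadian list stood at -0.48 in NZW/LacJ and at -0.79 in RIIIS/J, where 5 members were apart on the low side (Dbp, Tef, Usp2, Nr1d1 and Nr1d2) and Arntl on the high side. Alas1, the rhythmic first gene of heme synthesis, read 972 in NZW/LacJ and 1704 in RIIIS/J against 6217 to 12738.

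**Figure D3:**
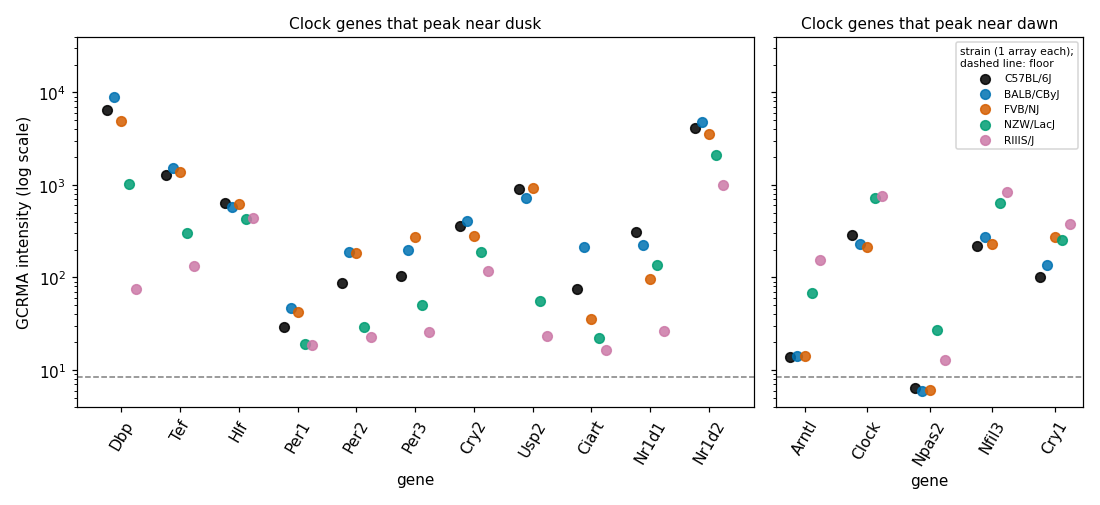
GCRMA intensity on a log scale of clock genes that peak near dusk (left) and near dawn (right), with 1 point per strain and a dashed line at the floor of 8.49. NZW/LacJ and RIIIS/J lie below the other 3 strains for 10 of 11 dusk genes, all but Nr1d1, and above them for 4 of 5 dawn genes, all but Cry1.

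Pairs of strains differed to unequal degrees. FVB/NJ and RIIIS/J were at least 2-fold apart in 1960 genes and FVB/NJ and NZW/LacJ in 1713, while C57BL/6J and BALB/CByJ were apart in 577. The remaining pairs had 855 (C57BL/6J and NZW/LacJ), 859 (NZW/LacJ and RIIIS/J), 983 (BALB/CByJ and NZW/LacJ), 1076 (C57BL/6J and RIIIS/J), 1269 (BALB/CByJ and RIIIS/J), 1280 (C57BL/6J and FVB/NJ) and 1312 (BALB/CByJ and FVB/NJ). Adjacent genes were called apart together in 96 pairs, against a median of 48 in shuffled gene orders, whose middle 95% ended at 61. Without pairs that share the first 3 letters of their names, many of them gene families, 67 pairs remained against an upper limit of 58. Of the 96 pairs FVB/NJ held 75, RIIIS/J 12, NZW/LacJ 6, C57BL/6J 2 and BALB/CByJ 2, with a pair able to count in more than 1 strain, and 31 pairs were counted when the FVB/NJ array was left out. The upper limits from shuffling were 52, 9, 4, 2 and 3 in the same order, so the counts of C57BL/6J and BALB/CByJ were not above theirs. Without shared first letters FVB/NJ had 53 pairs (limit 50), while RIIIS/J had 8 (limit 9), NZW/LacJ 4 (limit 4), C57BL/6J 1 (limit 2) and BALB/CByJ 1 (limit 3). Named pairs were Vnn3 with Vnn1 in C57BL/6J, Mup10 with Mup5 in BALB/CByJ, and Saa1 with Saa2 and Capn8 with Susd4 in NZW/LacJ, of which all but Capn8 with Susd4 share their first 3 letters. A further detected probe set deviated the same way in 356 of 412 calls, or 86.4% (95% Wilson interval 82.8% to 89.4%). A gene can be called in more than 1 strain. Over all strain values of 4557 genes that served as background the share was 66.9%. That background holds deviations of any size, whereas calls are at least 2-fold, so the 2 shares are not like for like. For calls of a higher gene the share was 85.6% and for calls of a lower gene 87.6%.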

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

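The comparison of the control signals reported here was chosen after they had been seen. The poly-A controls, transcripts added to the RNA before labelling, lie outside the strain comparisons and were above the mean of the other arrays for every one of their probe sets on 2 arrays, by a median of 1.74 on the log2 scale in NZW/LacJ and 0.36 in RIIIS/J. All 12 of these probe sets were highest in NZW/LacJ. The medians were -0.42 in C57BL/6J, -0.56 in BALB/CByJ and -1.07 in FVB/NJ. Hybridisation controls, added after labelling, stood at 0.25 in NZW/LacJ, less than its poly-A controls, and at 0.47 in RIIIS/J, more than its poly-A controls.

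Among liver transcripts the ratio of 3' to 5' signal for actin was highest in FVB/NJ at 4.98 and lowest in RIIIS/J at 2.76, while that for Gapdh ran from 0.90 to 1.01. Of the called genes in RIIIS/J with a further detected probe set, 83.3% had the same direction there and 46.1% deviated by at least 0.5 on the log2 scale.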

How the results depend on the processing

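The alternatives that leave out arrays were chosen after the data had been seen. Over the alternatives other than single probe sets, 903 gaps of named genes stayed at least 2-fold in the same direction, 38 were under 2-fold and 1 reversed. On single further probe sets of the named genes 47 stayed, 26 were under 2-fold and 1 reversed, and both reversals were of Hsd17b13. With no floor, quantile normalisation or the loess correction all 116 gaps stayed at least 2-fold. Among list medians 623 kept their call, 136 lost it with no change of sign and 29 changed sign. With the floor at the 99th percentile C57BL/6J had 33 lower genes, all among the main 50, agreement between probe sets was 91.0%, female-biased genes in RIIIS/J stood at -0.0048 and carboxylesterases in BALB/CByJ at 0.035. Without a floor agreement was 74.0%. With the mean of a gene's probe sets C57BL/6J had 28 lower genes, FVB/NJ had 40 lower genes, C57BL/6J and RIIIS/J differed in 716 genes, gluconeogenesis in RIIIS/J stood at -0.094 and the gap of Hsd17b13 in FVB/NJ was 0.28, and agreement could not be computed. A less intense probe set of Hsd17b13 gave a gap of at least 5.36. Without _s_at, _x_at and _a_at probe sets agreement was 82.6% and female-biased genes in RIIIS/J stood at -0.0048. Quantile normalisation gave 109 lower genes in FVB/NJ. At 4-fold the higher and lower genes numbered 11 and 4 in C57BL/6J, 18 and 14 in BALB/CByJ, 352 and 6 in FVB/NJ, 26 and 19 in NZW/LacJ, and 38 and 39 in RIIIS/J. Pairs at least 4-fold apart numbered 130 for C57BL/6J and BALB/CByJ, 484 for C57BL/6J and FVB/NJ, 174 for C57BL/6J and NZW/LacJ, 230 for C57BL/6J and RIIIS/J, 497 for BALB/CByJ and FVB/NJ, 229 for BALB/CByJ and NZW/LacJ, 303 for BALB/CByJ and RIIIS/J, 606 for FVB/NJ and NZW/LacJ, 674 for FVB/NJ and RIIIS/J, and 220 for NZW/LacJ and RIIIS/J. Against the median of the other strains BALB/CByJ had 7 lists apart, its carboxylesterases stood at 0.027 and proliferation in C57BL/6J at 0.010. Against C57BL/6J alone BALB/CByJ had 8 lists apart, with glucuronosyl- and sulfotransferases at 0.011, acute phase genes at 0.11 and erythroid genes at 0.34. In that setting fatty acid synthesis in FVB/NJ stood at -0.060, interferon-stimulated genes in NZW/LacJ at -0.086 and MHC class I in FVB/NJ at -0.011. The cause of these differences was not tested. Leaving out arrays moved values because a strain is compared with the others. Without FVB/NJ there were 31 adjacent pairs, and antigen-presenting genes stood at 1.61 in C57BL/6J and 0.14 in NZW/LacJ. T and NK genes then stood at 0.0061 in C57BL/6J and 0.020 in NZW/LacJ, interferon-stimulated genes in NZW/LacJ at -0.042, erythroid genes in BALB/CByJ at 0.0034 and proliferation in C57BL/6J at 0.055. Without RIIIS/J NZW/LacJ had 158 higher and 189 lower genes and its pancreatic list stood at 0.29. Without both, C57BL/6J had 105 higher and 95 lower genes, BALB/CByJ 165 and 108, and NZW/LacJ 202 and 261, with 39 adjacent pairs. Without both, antigen-presenting genes stood at 1.02 in C57BL/6J and 0.025 in NZW/LacJ, T and NK genes at 0.0091 in C57BL/6J and 0.017 in NZW/LacJ, and proliferation at 0.077 in C57BL/6J and 0.0079 in NZW/LacJ. In that setting interferon-stimulated genes in NZW/LacJ stood at -0.14, its pancreatic list at 0.21 and erythroid genes in BALB/CByJ at 0.12.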

Other observations

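The tests on acinar genes, time of day, poly-A controls and the 3 genotypes were chosen after the results had been seen, as was the comparison of strains 2 against 3. Some genes separated 2 strains from the other 3 rather than 1 from the rest. Cyp2c37, a cytochrome P450 gene, read 37234 in C57BL/6J and 47003 in RIIIS/J against 18.7 to 29.5 in the other strains, 1263-fold apart between the nearest strains of the 2 groups. In the same gene cluster Cyp2c39 was lower in both of these strains, at 6.25 and 19.5 against 157 to 631. Gdpd3, a lysophospholipase gene, was detected in FVB/NJ (1827) and RIIIS/J (1142) and under the floor in the other 3. Mndal, an interferon-inducible gene, was under the floor in those 2 strains and read 195 to 332 elsewhere. Pdxdc1 read 5.92 in BALB/CByJ and 9.79 in RIIIS/J against 454 to 585. Clec2h read 8.83 in BALB/CByJ and 9.24 in FVB/NJ against 250.0 to 636, and Cyp2c23 read 599 in BALB/CByJ and 420 in NZW/LacJ against 10473 to 10741. Abhd1 was lower in C57BL/6J and NZW/LacJ, at 54.0 and 35.6 against 905 to 1499.

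NZW/LacJ and RIIIS/J shared more genes in this way than any other pair, with 41 genes higher in both and 65 lower in both, against 38 genes in total for the next pair, BALB/CByJ and FVB/NJ. The clock gene Usp2 was among those lower in both. By the values given above, Dbp and Per2 were also lower on both arrays, and Clock and Nfil3 higher. How many of the shared genes follow the time of day of collection, rather than strain, was not tested. Hamp2, a hepcidin gene, read 40752 and 38310 against 2258 to 4695, while Hamp read 23410.0 to 53608 over the 5 strains. The glutathione transferase genes Gstm2 (182 and 217 against 1081 to 4041) and Gstm3 (271 and 71.2 against 1595 to 2629) were lower in both, and Gstm7 (4562 and 5196 against 633 to 1060) was higher. H2-Bl, an MHC class I gene, read 612 and 494 against 64.8 to 75.6.

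Lymphoid, erythroid and cell division genes were higher together in FVB/NJ. Lymph node RNA with no other source was set against erythroblast genes, which had a median of at least 0.84 in FVB/NJ, with 4 of 9 detected genes apart. That direction goes against lymph node RNA alone. Erythroid genes had already been seen higher there, so the outcome was likely in advance, and it cannot decide on lymph node RNA together with blood. A trend with signal level was argued against by the 711 genes called higher after the loess correction, which held all 690 called before it. Spleen RNA in the FVB/NJ pool stays a candidate explanation. Lists of follicle B cells (7 of 10 genes detected, median at least 4.76), erythroblasts (9 of 14) and megakaryocytes (5 of 8, median at least 3.53) all lay at or above the 99.95th percentile. Of their detected genes 2, 2 and 1 were above the floor on each other array, and 1, Tfrc, is in another list. These lists were chosen after lymphoid and blood genes had been seen higher in FVB/NJ, and genes counted only if detected on some array. High medians were thus likely in advance and add little to the first lists. The most abundant genes of the added lists besides Tfrc were Pf4 (1568), Cxcl13 (515) and Cr2 (417). Smooth muscle genes had a median of at least 0.33, and 0 of 4 genes of high endothelial venules were above the floor. The FVB/NJ genotype stays open, because there was 1 array of that strain.

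Exocrine pancreas genes were higher in RIIIS/J. The test set in advance used 13 islet genes and was left undecided, since only Iapp was above the floor, with a deviation of at least 0.59, so islet RNA stays open. Further acinar genes, a list added once that test was known to be undecided, had 11 of 17 detected and a median of at least 5.39 at the 100th percentile. Of its detected members 1 was above the floor on each other array and 0 were in another list. Ctrl (3777) and Ctrc (1027) were its most abundant genes. Klk1 was level at 43.0 to 52.3, and Erp27 was higher in NZW/LacJ (70.9) than in RIIIS/J (42.8). Acinar genes had already been seen apart in RIIIS/J, and genes counted only if detected on some array. A high median was thus likely in advance and adds little to the first list. Acinar RNA of the pancreas in the RIIIS/J pool stays a candidate explanation. The RIIIS/J genotype stays open with 1 array.

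Clock genes were apart in NZW/LacJ and RIIIS/J. A different amount of RNA relative to the poly-A controls, if it shifted all genes alike, would move both arms of the clock the same way. The median differences were -2.12 for dusk genes and 1.61 for dawn genes, which argues only against such a common shift. The opposite directions had already been seen, and whether the processing had removed a common shift was not examined. A different time of day of collection may underlie the pattern. On both arrays 90.9% of dusk genes lay below the other 3 strains and 80.0% of dawn genes above them. The directions were written down after the values were seen. All 11 dusk and 5 dawn genes belong to the circadian list already found apart, so these shares restate that pattern. Strain genotype stays open, because no strain had more than 1 array and the hour of collection was not given in the sources used here.

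Hypotheses on single genes and probes were left undecided. Reduced ZHX2 activity in BALB/CByJ could raise Lpl, Gpc3 and H19, and 1 of the 2 genes analysed here was at least 2-fold higher, Lpl, while Gpc3 was under the floor and H19 was not analysed here. A sequence difference under the Zhx2 probe set could not be examined, as 0 other Zhx2 probe sets were above the floor. Sequence differences under the probes could lower signals in single strains and would then leave the further probe sets of lower genes in less agreement. Their share was 87.6% (81.8% to 91.7%) for lower genes and 85.6% (80.6% to 89.5%) for higher genes, and the intervals overlapped. At a deviation of at least 0.5 on the log2 scale the shares were 58.6% and 71.6%, and 55.6% and 64.1% over the strains other than FVB/NJ.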
